A study of Mus musculus with 23 samples.

How the data were processed

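RNA was sequenced from micro-dissected knee cartilage of male mice, wild type (WT, labelled TET1+/+) or Tet1 mutant (labelled TET-/-, called KO here), after destabilization of the medial meniscus (DMM, an operation that induces osteoarthritis) or sham surgery, collected 6 or 12 weeks after an operation at 3 to 4 months of age. The labels give 23 samples in 8 groups, with 3 samples in each group except WT sham at 6 weeks, which has 2. Groups and replicate numbers were taken from the sample titles. The labels call the sham contralateral in a protocol and age-matched in the series record. Whether sham and DMM knees come from the same mice is therefore not settled. Per the labels' protocols, libraries were made with a SMART-seq2 kit and the libraries of each time point were pooled and sequenced together, so time and sequencing run change together.

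Per the submitters' processing notes, CASAVA 1.4, Trimmomatic, HISAT2 and DESeq2 were used with the mouse genome build mm10, and the program that assembled the transcripts and counted reads is not given in the sources used here. The authors deposited a table of estimated counts per transcript model, as whole numbers, not normalized, with 90308 rows and a column for each of the 23 samples. Of the rows, 63758 carry a UCSC transcript name and 26550 a name that starts with MSTRG, the form given to assembled transcripts, and 7414 rows hold 0 in every column. Transcript models of a locus share exons, so the counts depend on how reads were divided among them, and the counts were treated as estimated counts and used as whole numbers. The authors also deposited 4 tables of comparisons with, per the file headers, a mean of normalized counts, a log2 fold change with its standard error, a p-value and an adjusted p-value for each transcript.

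The deposited tables do not pair the transcript names with genes, and 0 of the 90308 names were found in the reference gene tables used here. No gene is therefore named, the level of Tet1 could not be read as a check on the genotype labels, and the gene lists fixed before the data were examined (cartilage matrix, matrix-degrading enzymes, cell type markers and others) were not tested. The rule for named genes, fixed at the same time, listed Tet and Dnmt genes, reference genes of cartilage, members of the fixed lists, and genes with an adjusted p below 0.05, a mean log2 CPM of at least 1 and replicate ranges that do not overlap, by largest fold change. Where fewer than 10 genes passed, it took those that passed and the 5 with the smallest p in each direction. It excluded bare identifiers and so names none here. The last 2 parts, applied to transcripts without that exclusion, supplied at most 2 transcripts in each direction per comparison.

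The columns were compared before any test. WT sham replicate 1 at 6 weeks did not line up with its row names: its Spearman correlation with the other columns was 0.0149 to 0.0294 across 53502 transcripts with a mean count above 20, against 0.610 to 0.764 among the other 22 columns. In 90 windows of 1000 rows, the row offset that best matched this column to the mean of the others ranged from -16 to 6 and was 0 in 4 windows, whereas it was 0 in all 90 windows for WT sham replicate 3. The column was kept out of the main fits, a departure from the design fixed before the data were examined, and was not realigned. WT sham at 6 weeks then had 1 library, assumed to vary like the other groups. No 2 columns held identical values, and replicates differed far beyond counting error (lowest chi-square per degree of freedom 268).

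Each of the authors' 4 tables gives the mean normalized count of the libraries that entered it. For both tables of KO against WT DMM these were the 6 DMM columns. For both tables with WT sham at 6 weeks they were the 3 WT DMM columns, WT sham replicate 3 and another library. Subtracting the known columns gave counts of that library that were whole within 0.0001 for every row and identical between both tables. This recovered library matched no column and entered only alternatives chosen after seeing the data. It held 5.87 M counts and 29082 detected transcripts, and which sample it is was not worked out. Fits with it keep WT sham replicate 3, so overlaps with the main calls are not independent checks.

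Main tests used edgeR 4.0.16 in R 4.3.3: TMM normalization, the package's filter on low counts by group, a negative binomial fit with 1 mean per group, robust quasi-likelihood tests and Benjamini-Hochberg adjustment, with calls at an adjusted p below 0.05. The 10 usable libraries at 6 weeks and the 12 at 12 weeks were fitted separately, with 61212 and 57350 transcripts tested, and the comparison across times used all 22 with 67238 tested. The common dispersion was 1.47, 1.18 and 1.40. Counts of transcripts at an unadjusted p below 0.05 are to be read against the share of 0.05 expected of unchanged transcripts. In the main fits only KO against WT DMM at 6 weeks (3708 of 61212) and the comparison across times (4857 of 67238) exceeded that share. CPM values are counts divided by the column total, on the usual scale. A fold against a group with no counts is given as a bound, from the mean over its libraries of the level that 3 counts represent. Such floors and all intervals cover counting error only, and the intervals of shares of signs treat transcripts as independent, which they are not. The series record calls the samples of a group biological replicates.

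Alternatives fixed before the data were examined were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, no filter on low counts, a replicate block, all usable libraries in 1 fit (or only the libraries compared) and leaving out each replicate. The block was genotype and number for DMM against sham and for the interaction. For the other comparisons it was the number alone, which joins mice of different genotypes. Shares of opposite or same signs were set beside 20 simulations per time point of unchanged groups that share the WT DMM libraries. Checks without a model counted transcripts with a mean above 1 CPM whose values do not overlap between sets of libraries, over all splits.

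The fits were tested on simulated data drawn from the means, depths and fitted spread of the real libraries, with 200 changed transcripts. Of these, 50 were changed by each of 4, 16, 64 and 256-fold. For KO against WT DMM at 6 weeks edgeR recovered 0, 1, 2 and 11 of each 50, with 14 called and 0 of them unchanged, and DESeq2 recovered 5, 29, 38 and 41, with 968 called, of which 855 were unchanged. At 12 weeks edgeR recovered 1, 9, 24 and 24, with 58 called and 0 unchanged, and DESeq2 recovered 9, 42, 41 and 40, with 813 called, of which 681 were unchanged. Simulated unchanged groups gave edgeR 0 calls. Other splits of the real KO DMM and KO sham libraries at 12 weeks gave a median of 13 and up to 26. The simulations do not reproduce this, so the 0 unchanged may not hold for the real libraries. A first round with 4 and 16-fold changes only had recovered few by edgeR, and the larger changes were then added. Tables and plots were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.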

Results

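Transcript abundance was measured in cartilage from the knees of WT and Tet1 mutant (KO) male mice, 6 or 12 weeks after DMM or sham surgery. Tet1 encodes an enzyme that oxidizes 5-methylcytosine to 5-hydroxymethylcytosine in DNA. Each group had 3 libraries except WT sham at 6 weeks, which had 2, and the counts of 1 of these did not line up with the transcript names and were left out. Column totals of the 22 usable libraries ranged from 34.9 M to 85.7 M counts at 6 weeks and from 46.5 M to 113 M at 12 weeks. At these depths 3 counts correspond to between 0.0266 and 0.0860 CPM. The assembled transcripts took 22.8% to 27.3% of the counts of a usable library. Replicates of a group had Spearman correlations of 0.667 to 0.754 across transcripts, which are not independent replicates.

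**Figure D1:**
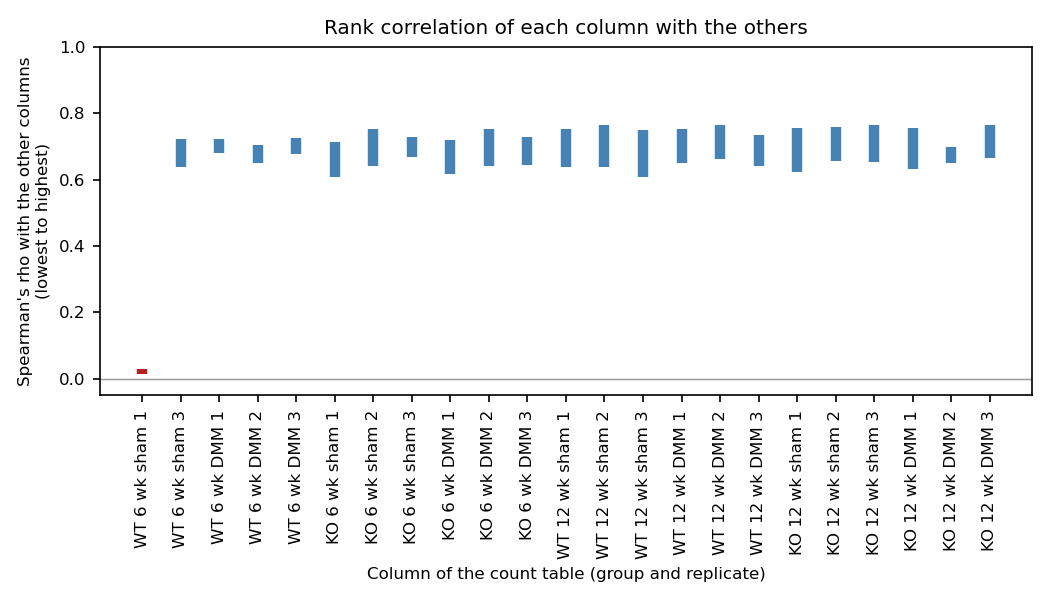
Range of Spearman's rho, from lowest to highest, between each column of the count table and the other usable columns, by group and replicate. WT sham replicate 1 at 6 weeks lies between 0.0149 and 0.0294, and the other 22 columns correlate at 0.610 to 0.764.

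The first comparison asked how Tet1 loss changed expression in operated knees. At 6 weeks, the assembled transcript MSTRG.12681.1 was at 48.2 ± 4.77 CPM (SD, n = 3) in KO DMM and at 0 in the 3 WT DMM libraries, at least 886-fold higher in KO (edgeR adjusted p = 0.00642). It was also at 51.8 ± 10.7 CPM (SD, n = 3) in KO sham and at 0 in the WT sham library. MSTRG.2007.18 was at 86.8 ± 6.44 CPM (SD, n = 3) in WT DMM and at 0 in KO DMM, at least 1819-fold lower in KO (edgeR adjusted p = 0.00642). MSTRG.2007.17, an assembled transcript of the same locus chosen after its values were seen, was at 51.7 CPM in KO DMM and 0.458 CPM in WT DMM, so that the sum of both was 51.7 ± 30.3 CPM (SD, n = 3) in KO DMM and 87.3 ± 6.37 CPM (SD, n = 3) in WT DMM. MSTRG.1736.1 was at 31.4 ± 4.54 CPM (SD, n = 3) in WT DMM and at 0 in KO DMM, at least 657-fold lower (edgeR adjusted p = 0.0117). In total, 1 transcript rose and 3 fell in KO DMM against WT DMM by edgeR, with 3708 of 61212 at an unadjusted p below 0.05. The DESeq2 Wald test on the same libraries called 2140, and the authors' deposited table called 2521 (1004 higher, 1517 lower) at an adjusted p below 0.05. All 4 edgeR calls were among those of the authors' deposited table. With the replicate number as a block edgeR called 0 (3201 at an unadjusted p below 0.05). With the misaligned WT sham column as deposited, which is in neither group compared, edgeR also called 0 (2118 at an unadjusted p below 0.05). Without WT DMM replicate 2 it called 10, and without KO DMM replicate 2 it called 7. MSTRG.1736.1 did not pass without WT DMM replicate 1 or 3 (edgeR adjusted p = 0.0542 and 0.0616), in a range over all alternatives from 1.09e-24 by DESeq2 to 1. MSTRG.12681.1 did not pass with all usable libraries in 1 fit (edgeR adjusted p = 0.368), where edgeR called 81 transcripts, 1 of them among the 4. MSTRG.2007.18 did not pass with the library recovered from the authors' tables (edgeR adjusted p = 0.945), where edgeR called 2 transcripts, both among the 4. The adjusted p over all alternatives ranged up to 1 for both, from 8.06e-27 and 1.42e-30 by DESeq2.

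At 12 weeks, MSTRG.2642.1 was at 4.51 ± 1.49 CPM (SD, n = 3) in KO DMM and 0.104 ± 0.00376 CPM (SD, n = 3) in WT DMM, a log2 fold change of 5.35 (SE 0.52, edgeR adjusted p = 0.0300). The transcript uc009fzx.3 was at 12.2 ± 7.13 CPM (SD, n = 3) in WT DMM and at 0 in KO DMM, at least 281-fold lower (edgeR adjusted p = 0.0300). The transcript uc008vvl.1 was at 1.29 ± 0.242 CPM (SD, n = 3) in WT DMM and at 0 in KO DMM, at least 29.8-fold lower (edgeR adjusted p = 0.0300). In total 1 transcript rose and 4 fell by edgeR, with 2268 of 57350 at an unadjusted p below 0.05, fewer than the share of 0.05 expected of unchanged transcripts. DESeq2 called 1276, and the authors' deposited table called 815 (416 higher, 399 lower). All 5 edgeR calls were among those of the authors' deposited table. edgeR called 0 without WT DMM replicate 3 (2001 at an unadjusted p below 0.05), 0 without a filter on low counts (2757), 0 with the replicate block (1474) and 0 with all usable libraries in 1 fit (2700). It called 12, 14, 35, 12 and 34 without WT DMM replicate 1 or 2 or KO DMM replicate 1, 2 or 3, in that order. MSTRG.2642.1 did not pass without WT DMM replicate 1, 2 or 3 (edgeR adjusted p from 0.0694 to 0.104, and from 1.09e-30 by DESeq2 to 0.936 over all alternatives).

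Of the 4 transcripts called at 6 weeks, 1 had the same direction at 12 weeks, and 0 were called at both times by edgeR. MSTRG.12681.1, at 0 in WT at 6 weeks, was at 23.4 ± 12.1 CPM (SD, n = 3) in WT DMM and 28.3 ± 24.9 CPM (SD, n = 3) in KO DMM at 12 weeks. At that time it was at 0 in WT sham replicate 3, KO sham replicates 1 and 3 and KO DMM replicate 1. MSTRG.1736.1, at 0 in KO DMM at 6 weeks, was at 46.5 ± 5.99 CPM (SD, n = 3) in KO DMM at 12 weeks. At that time it was at 0 in WT sham replicate 3 and WT DMM replicate 2. MSTRG.2642.1, called at 12 weeks, was at 3.48 ± 2.88 CPM (SD, n = 3) in WT DMM and 4.07 ± 1.43 CPM (SD, n = 3) in KO DMM at 6 weeks. The WT DMM replicates 2 and 3 at 6 weeks were at 0 for uc009fzx.3, with replicate 1 at 3.83 CPM. For uc008vvl.1, WT DMM replicates 1 and 2 were at 0 at 6 weeks, with replicate 3 at 1.14 CPM. Of the 200 transcripts with the smallest p at 6 weeks, 53.5% had the same sign at 12 weeks (exact Clopper-Pearson 95% interval 46.3% to 60.6%).

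**Figure D2:**
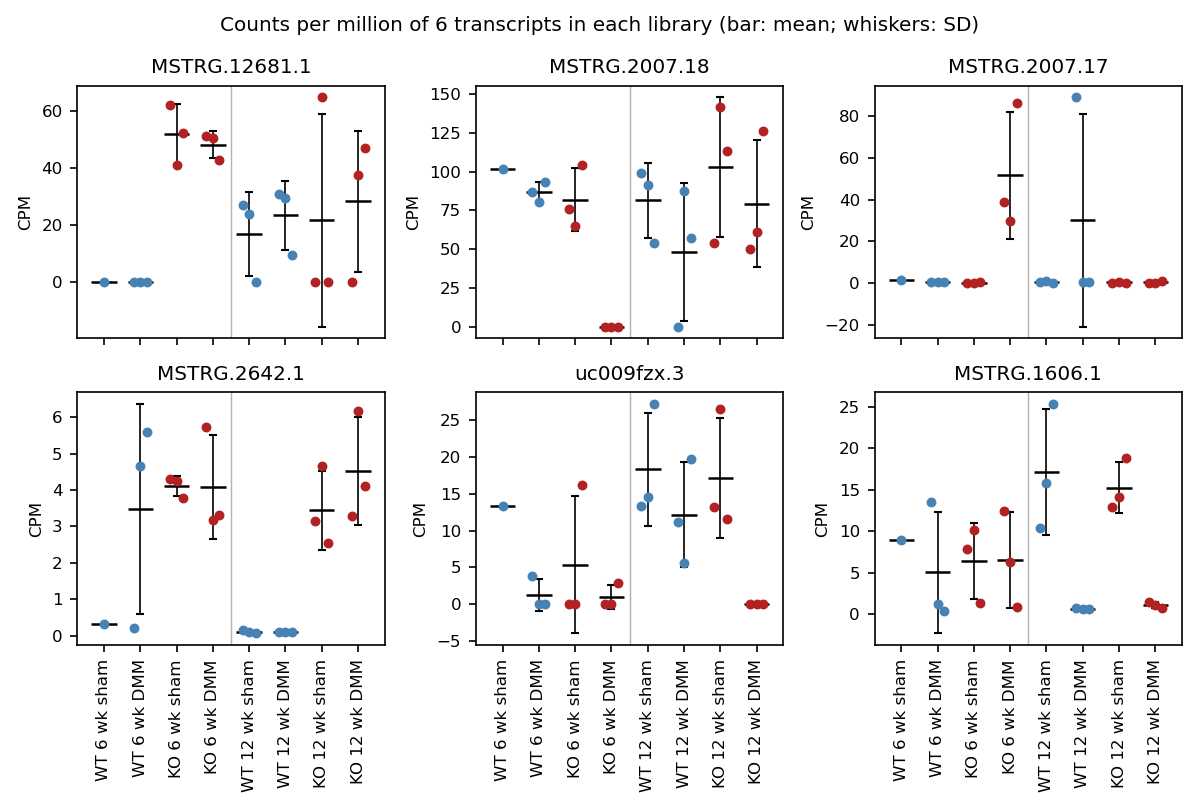
CPM of 6 transcripts in each usable library (points, WT blue and KO red) by genotype, time and surgery, with the group mean (horizontal bar) and SD (whiskers). MSTRG.2007.18 lies at 0 in the 3 KO DMM libraries at 6 weeks, where MSTRG.2007.17 has a mean of 51.7 CPM, and MSTRG.1606.1 lies at 0.644 to 1.47 CPM in the DMM libraries at 12 weeks.

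Sham-operated knees of KO and WT mice were compared for a difference between genotypes. A protocol calls the sham contralateral, so these knees may come from mice with DMM in the other knee. A direction shared with DMM knees would then not be an independent result. At 12 weeks uc011wio.2 was at 2.72 ± 0.335 CPM (SD, n = 3) in KO sham and at 0 in WT sham, at least 102-fold higher (edgeR adjusted p = 0.0105). MSTRG.2642.1 was at 3.45 ± 1.09 CPM (SD, n = 3) in KO sham and 0.101 ± 0.0366 CPM (SD, n = 3) in WT sham, a log2 fold change of 4.99 (SE 0.51, edgeR adjusted p = 0.0485), the same direction as in DMM knees at 12 weeks. It did not pass without a filter on low counts (edgeR adjusted p = 0.0629) or without KO sham replicate 2 or 3 or any of the 3 WT sham replicates (edgeR adjusted p from 0.0536 to 0.174, and from 1.37e-27 by DESeq2 to 0.340 over all alternatives). Altogether 3 transcripts rose and 0 fell, with 2436 at an unadjusted p below 0.05 by edgeR and 1236 called by DESeq2. edgeR called 0 with the replicate block (1513 at an unadjusted p below 0.05), 0 with all usable libraries in 1 fit (2924), 1 without a filter on low counts, 14 without KO sham replicate 1 and 5 without WT sham replicate 3. At 6 weeks 93 rose and 10 fell by edgeR and 3362 were called by DESeq2. That comparison rests on 1 WT sham library. edgeR called 0 with the misaligned WT sham column as deposited (6856 at an unadjusted p below 0.05), 1 with the replicate block, 31 without KO sham replicate 3 and 62 without KO sham replicate 2. With the recovered library it called 115, 67 of them among the 103. With all usable libraries in 1 fit it called 289 (223 higher, 66 lower), 59 of them among the 103.

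Expression after DMM was compared with sham within WT mice. At 12 weeks MSTRG.1606.1 was at 0.685 ± 0.0582 CPM (SD, n = 3) in WT DMM and 17.2 ± 7.59 CPM (SD, n = 3) in WT sham, a log2 fold change of -4.67 (SE 0.44, edgeR adjusted p = 0.0392). The transcript uc011wio.2 was at 2.28 ± 0.528 CPM (SD, n = 3) in WT DMM and at 0 in WT sham, at least 85.5-fold higher (edgeR adjusted p = 0.0117). These were the only transcripts called by edgeR, with 1892 at an unadjusted p below 0.05, and DESeq2 called 1086. The call of MSTRG.1606.1 was lost without WT sham replicate 2 or any of the 3 WT DMM replicates, with edgeR adjusted p from 0.0809 to 0.124 and log2 fold changes from -4.74 to -4.64, and without a filter on low counts (0.0501), where edgeR called 1 transcript. Over all alternatives its adjusted p ranged from 1.07e-28 by DESeq2 to 1. The call of uc011wio.2 rests on the same 3 WT sham libraries at 0 as its call in KO against WT sham. The transcript uc011wio.2 did not pass without WT sham replicate 2 (edgeR adjusted p = 0.0634, and from 1.57e-14 by DESeq2 to 1 over all alternatives). edgeR then called 0 (1806 at an unadjusted p below 0.05), and it called 10, 11, 4 and 6 without WT DMM replicate 1, WT DMM replicate 2, WT sham replicate 1 and WT sham replicate 3. It called 0 with the replicate block (1400 at an unadjusted p below 0.05) and 0 with all usable libraries in 1 fit (2388).

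At 6 weeks 92 transcripts rose and 8 fell in WT DMM against the single usable WT sham library by edgeR, with no other column of the count table to check the sham side. MSTRG.7490.15 was at 100 ± 28.6 CPM (SD, n = 3) in WT DMM and at 0 in that library, at least 1317-fold higher, and MSTRG.14018.5 was at 89.8 ± 13.6 CPM (SD, n = 3), at least 1183-fold higher (edgeR adjusted p = 0.0201 and 0.00280). At 12 weeks MSTRG.7490.15 was also at 0 in WT DMM replicate 1 and KO DMM replicate 2, so its 0 in 1 sham library may not mark surgery. MSTRG.14018.5 was detected in every other usable library. MSTRG.9655.8 was at 16.3 CPM in the sham library and at 0 in WT DMM, at least 300.0-fold lower (edgeR adjusted p = 0.0386). This call was lost without WT DMM replicate 1, 2 or 3 (edgeR adjusted p = 0.0850, 0.0619 and 0.0806), with all usable libraries in 1 fit (0.390) and with the recovered library (0.336), in a range over all alternatives from 8.20e-12 by DESeq2 to 0.552. At 12 weeks MSTRG.9655.8 was at 0 in WT sham replicate 3 and KO sham replicates 1 and 3. MSTRG.7490.15 did not pass with all usable libraries in 1 fit (edgeR adjusted p = 0.712, and from 9.59e-12 by DESeq2 over all alternatives). DESeq2 called 3008, and the authors' deposited table called 2742 (1866 higher, 876 lower). Of the 100 edgeR calls, 72 were among those of the authors' deposited table. edgeR called 0 with the misaligned WT sham column as deposited (6739 at an unadjusted p below 0.05), 0 with the replicate block (2558), 17 without WT DMM replicate 1 and 44 without WT DMM replicate 3. With the recovered library as another WT sham library it called 105 (104 higher, 1 lower), 64 of them among the 100. That library holds 5.87 M counts and 29082 detected transcripts, against 45103 in WT sham replicate 3 thinned to the same depth. Transcripts missing from it may add to the calls higher in DMM. WT sham replicate 3 stays in this fit, so the overlap is not an independent check. With all usable libraries in 1 fit edgeR called 247 (210 higher, 37 lower), 54 of them among the 100. Against the same sham library, WT DMM at 12 weeks had 242 transcripts higher and 44 lower by edgeR, DESeq2 called 6096, and the authors' deposited table for that comparison called 5226 (3590 higher, 1636 lower). With the recovered library edgeR called 565 (370 higher, 195 lower), 183 of them among the 286, and with the misaligned column as deposited 1944 (551 higher, 1393 lower), 165 of them among the 286. Time after surgery and sequencing run change together with surgery in that comparison, and edgeR called 0 when only the libraries compared entered the fit (6494 at an unadjusted p below 0.05).

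Within KO mice, MSTRG.2007.18 was at 81.8 ± 20.3 CPM (SD, n = 3) in sham and at 0 in DMM at 6 weeks, at least 1713-fold lower (edgeR adjusted p = 0.00849). The sum with MSTRG.2007.17 was 82.1 ± 20.5 CPM (SD, n = 3) in sham and 51.7 ± 30.3 CPM (SD, n = 3) in DMM. MSTRG.1736.1 was at 43.3 ± 13.4 CPM (SD, n = 3) in sham and at 0 in DMM, at least 907-fold lower (edgeR adjusted p = 0.0157). Both transcripts were also called in KO against WT DMM, from the same 3 KO DMM libraries at 0. The calls are therefore not separate results for genotype and for surgery. Here 0 rose and 3 fell by edgeR, with 2119 at an unadjusted p below 0.05, and DESeq2 called 1039. edgeR called 0 without KO sham replicate 2 (2416 at an unadjusted p below 0.05), 5 without KO DMM replicate 1 and 7 without KO DMM replicate 2. With the replicate block edgeR called 0 (1822 at an unadjusted p below 0.05), and with all usable libraries in 1 fit it called 10, 0 of them among the 3. It called 0 with the misaligned WT sham column as deposited (1723) and 1 with the recovered library, neither of which is in the groups compared. At 12 weeks uc009fzx.3 was at 17.1 ± 8.17 CPM (SD, n = 3) in KO sham and at 0 in KO DMM, at least 395-fold lower, and uc008vvl.1 was at 1.36 ± 0.263 CPM (SD, n = 3) in KO sham and at 0 in KO DMM, at least 31.5-fold lower (edgeR adjusted p = 0.0358 for both). These 2 were the only edgeR calls, with 2270 at an unadjusted p below 0.05, and DESeq2 called 1317. Both were also called in KO against WT DMM at 12 weeks, from the same 3 KO DMM libraries at 0. Neither passed without KO sham replicate 2 (edgeR adjusted p = 0.0532 for both, and over all alternatives up to 1, from 3.52e-18 for uc009fzx.3 and 5.12e-11 for uc008vvl.1 by DESeq2). edgeR called 0 with the replicate block (1561 at an unadjusted p below 0.05) and 0 with all usable libraries in 1 fit (2704). It called 14, 7, 34, 17 and 37 without KO sham replicate 1 or 3 or KO DMM replicate 1, 2 or 3, in that order. MSTRG.1606.1, which fell in WT DMM, was at 1.11 ± 0.368 CPM (SD, n = 3) in KO DMM and 15.3 ± 3.10 CPM (SD, n = 3) in KO sham, a log2 fold change of -3.85 (SE 0.43) that did not pass (edgeR adjusted p = 0.0515).

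**Figure D3:**
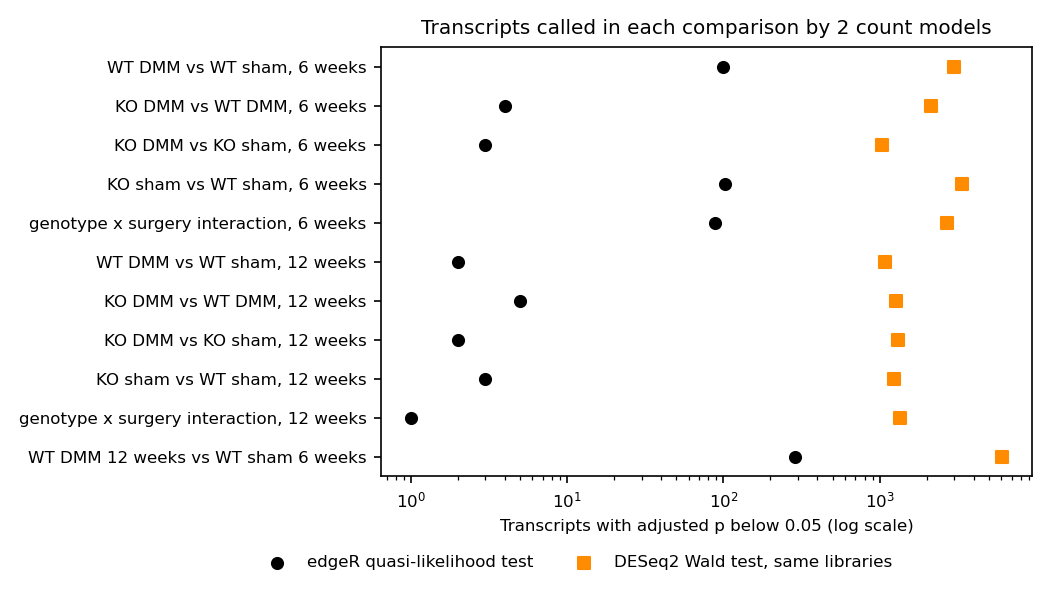
Number of transcripts with an adjusted p below 0.05 in each comparison, on a log scale, by the edgeR quasi-likelihood test (circles) and the DESeq2 Wald test on the same libraries (squares). edgeR counts run from 1 to 286 and DESeq2 counts from 1039 to 6096.

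The response to DMM was compared between genotypes. The genotype by surgery interaction called 89 transcripts at 6 weeks (8 higher, 81 lower) and 1 at 12 weeks by edgeR, and 2693 and 1342 by DESeq2. The 12-week call was uc011wio.2, at 0 in WT sham and at 2.28 to 2.74 CPM on average in the other 3 groups (edgeR adjusted p = 0.0283). It did not pass without a filter on low counts (edgeR adjusted p = 0.0532), where the interaction called 0 (2977 at an unadjusted p below 0.05), or without WT sham replicate 2, WT DMM replicate 3 or KO sham replicate 2 or 3 (edgeR adjusted p from 0.0507 to 0.0981, and from 4.02e-14 by DESeq2 to 1 over all alternatives). The interaction at 12 weeks called 24, 9 and 21 without KO DMM replicate 1, 2 and 3, 8, 14 and 0 without WT DMM replicate 1, 2 and 3 (2288 at an unadjusted p below 0.05 in the last), 5 and 3 without KO sham replicate 1 and 3, and 3 and 4 without WT sham replicate 1 and 3 by edgeR. The 6-week count rests on the single WT sham library and was 16 and 7 without WT DMM replicate 1 and 3, 8 and 20 without KO sham replicate 2 and 3, and 22 and 18 without KO DMM replicate 2 and 3. edgeR called 0 with the misaligned WT sham column as deposited (5562 at an unadjusted p below 0.05), and 87 with the recovered library, 57 of them among the 89. With the replicate block the interaction called 0 at 6 weeks (2766 at an unadjusted p below 0.05) and 0 at 12 weeks (1314) by edgeR, and with all usable libraries in 1 fit 207 at 6 weeks, 45 of them among the 89, and 0 at 12 weeks (2856). Of the 100 transcripts called in WT DMM against sham at 6 weeks, 50 had the same sign in KO DMM against KO sham (exact Clopper-Pearson 95% interval 39.8% to 60.2%), and 0 were called in both by edgeR. Of the 200 with the smallest p at 12 weeks, 52.5% had the same sign (45.3% to 59.6%). Reversal was read as an opposite sign in KO DMM against WT DMM. It was seen for 64 of the 100 called transcripts at 6 weeks (53.8% to 73.4%), with 0 called in both by edgeR. Of the 200 with the smallest p, 62.5% had opposite signs at 6 weeks (55.4% to 69.2%) and 75.5% at 12 weeks (68.9% to 81.3%). Unchanged groups that share the WT DMM libraries gave 76.5% to 83.5% and 84.0% to 94.0% in 20 simulations each. Both observed shares lie below these ranges, and the 6-week simulations called 0 transcripts in WT DMM against sham, where the real fit called 100. The simulations thus differ from the real data, and the comparison does not decide whether DMM effects were reversed. For the same sign in KO DMM against KO sham, the simulations gave 43% to 61% at 6 weeks and 44% to 54% at 12 weeks, over the 200 with the smallest p.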

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

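The tests on transcripts that separate the genotypes, on transcripts at 0 in a group and on the change between time points, and the fits with the recovered library or with DESeq2 on the 2 groups, were chosen after the result was seen. Splits of the libraries for the fitted comparisons, and the tests on loci and single libraries, were written down before their results. No group has 4 samples, so single samples were not tested as outliers.

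The genotype by surgery interaction called 89 transcripts at 6 weeks and 1 at 12 weeks by edgeR, as a test of whether the response to surgery differs between genotypes. With the replicate block edgeR called 0 at 6 weeks (2766 at an unadjusted p below 0.05, and 2693 called by DESeq2 without the block) and 0 at 12 weeks (1314, and 1342 by DESeq2). The block leaves fewer degrees of freedom, so these counts of 0 cannot tell an effect of pairing from lost power. At 6 weeks WT sham has 1 usable library, so regroupings were not run. At 12 weeks every one of the 40 regroupings drawn, the real one included, gave at least 1 call, with up to 19 in the others, so chance cannot be excluded. The genotype effect in DMM knees differed between 6 and 12 weeks for 20 transcripts (5 higher, 15 lower at 6 weeks relative to 12) by edgeR over all 22 usable libraries. No alternative was run for this count. With all usable libraries in 1 fit, KO against WT DMM had 81 calls at 6 weeks and 0 at 12 weeks, against 4 and 5 in the main fits.

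A library outside the count table appeared in both of the authors' tables that use WT sham at 6 weeks. Its recovered counts sum to 5869194, below the total of any column, and cover 29082 transcripts. Its Spearman correlation with the usable columns was 0.415 to 0.505, against 0.637 to 0.720 for WT sham replicate 3 thinned to the same depth. DESeq2 on the 2 groups with this library called 2689 transcripts in WT DMM against sham at 6 weeks, 2671 of them among the 2742 of the authors' table. Without it DESeq2 called 4693, of which 2047 were among the authors'. Which sample it is was not worked out.

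The authors' tables call 2521 transcripts in KO against WT DMM at 6 weeks and 815 at 12 weeks, where edgeR called 4 and 5, and DESeq2 on the 6 libraries gave 2527 and 805. The other 9 splits of the same libraries gave 774 to 1364 at 6 weeks and 847 to 2340 at 12 weeks (1 and 10 of 10 splits as large as the real one, too few splits for a share under 0.05). The split with 2340 calls, the highest of 10, set KO replicates 1 and 2 and WT replicate 3 against the others, a possible sign of some structure of the samples, which was not tested. Calls resting on 1 library of a group and changes of transcript within a locus stay open beside an effect of genotype: 87.3% of the authors' calls at 6 weeks and 78.0% at 12 weeks had CPM ranges that do not overlap (chance gives 10% for 3 against 3 among unselected transcripts, which is no chance level for transcripts called between these same groups), and 48.2% and 65.2% of called assembled transcripts with a called sibling had one moving the opposite way, against 47.6% to 70.0% and 44.6% to 73.9% after shuffling directions. At 6 weeks the share lay below the shuffled median of 59.4%, the bound written beforehand against the locus account, but within the shuffled range.

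Among transcripts with a mean above 1 CPM, 977 of 39074 separated all 6 KO from all 4 usable WT libraries at 6 weeks, and 159 of 40066 separated 6 from 6 at 12 weeks. At 6 weeks 5 of all 210 splits separated as many, and 33 of 462 did at 12 weeks. The highest other count at 6 weeks was 1360, with KO replicates 2 and 3 against the others. At 12 weeks it was 898, with KO replicates 2 and 3 and WT replicate 1 against the others, other libraries than in the highest DESeq2 split. The genotype split keeps libraries of the same genotype and number together. Such splits separated a median of 602.5 at 6 weeks, against 300 over all splits, so the 5 of 210 cannot exclude chance. Depth is argued against at 6 weeks, where the highest KO total, 70.4 M counts, lies above the lowest WT total, 34.9 M, but at 12 weeks the highest KO total, 93.0 M, lies below the lowest WT total, 96.2 M, so depth and genotype cannot be told apart there. Libraries of the same genotype and number resembled each other weakly. Each of 9 pairs deviated together with a positive correlation (0.0320 to 0.181), 3 of them over 0.1. In 9 of 9 the DMM library correlated best with the sham library of its own number. Whether a number marks an animal is not settled. Of 10 splits that keep these libraries together, 3 separated as many at 6 weeks and 4 at 12 weeks. Differences between a few animals could give this as well as an effect of genotype. At both times 3 transcripts were higher and 1 lower in KO among those separated, against 1.06 and 0.677 by chance.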

How the results depend on the processing

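Fits with the recovered library and with DESeq2 on the 2 groups were chosen after seeing the data, the others before. Leaving WT sham replicate 1 at 6 weeks out of the main fits was also chosen after seeing the data. The fit with that column as deposited follows the design fixed beforehand. Comparisons are given in the order WT DMM vs sham, KO vs WT DMM, KO DMM vs sham, KO vs WT sham and interaction, with main counts of 100, 4, 3, 103 and 89 at 6 weeks, 2, 5, 2, 3 and 1 at 12 weeks, and 286 for WT DMM at 12 weeks vs WT sham at 6 weeks. DESeq2 size factors gave 99, 4, 3, 104 and 89, then 2, 5, 2, 4 and 1, and 286. The DESeq2 test called 3008, 2140, 1039, 3362 and 2693 at 6 weeks, 1086, 1276, 1317, 1236 and 1342 at 12 weeks, and 6096 across times. On the 2 groups alone it called 4693, 2527, 722 and 4429 at 6 weeks, 1001, 805, 794 and 1274 at 12 weeks, and 7721 across times. With the recovered library it called 2689 in WT DMM vs sham, 2658 in KO vs WT sham and 5353 across times. Simulated data gave DESeq2 many calls of unchanged transcripts, and edgeR recovered 1 and 9 of 50 transcripts changed 16-fold at 6 and 12 weeks, so changes of this size were mostly not detectable by edgeR with the fitted spread between replicates.

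Without a filter on low counts, the 12-week counts were 1 for WT DMM vs sham, 0 for KO vs WT DMM, 1 for KO vs WT sham and 0 for the interaction. All usable libraries in 1 fit gave 247, 81, 10, 289 and 207 at 6 weeks and 0, 0, 0, 0 and 0 at 12 weeks, and only the libraries compared gave 0 across times. With the misaligned column as deposited, each 6-week count was 0 and the count across times 1944. With the recovered library in edgeR, WT DMM vs sham had 105 (64 among the main calls), KO vs WT sham 115 (67), the interaction 87 (57), KO vs WT DMM 2, KO DMM vs sham 1 and the comparison across times 565 (183). The cause was not tested.

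With the replicate block, edgeR called 1 in KO vs WT sham at 6 weeks, 235 across times and 0 in every other comparison, where 1314 to 3201 transcripts had an unadjusted p below 0.05. For KO vs WT and across times the block was the number alone. It then joins different mice, so these counts do not show a loss of calls under a real pairing. The labels call the sham contralateral in a protocol and age-matched in the series record, and do not state that a number marks an animal. Of 9 pairs of DMM and sham libraries of a genotype and number, 3 deviated together with a correlation over 0.1 (range 0.0320 to 0.181), under the bound of 0.1 for every pair that would have made the number a pairing, so the fits without the block were kept. A pairing is not excluded, since a protocol calls the sham contralateral and each r was positive. In addition, 9 of 9 DMM libraries correlated best with the sham library of their own number. If the pairing is real, the main fits of DMM vs sham and of the interaction ignore it. With the block these comparisons called 0. The block leaves fewer degrees of freedom, and at 6 weeks only WT replicate 3 had both a usable sham and a DMM library. The counts of 0 therefore cannot tell an effect of pairing from lost power.

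Leaving out each replicate in turn gave 17 to 96, 4 to 10, 0 to 7, 31 to 114 and 7 to 92 calls at 6 weeks, 0 to 11, 0 to 35, 2 to 37, 3 to 14 and 0 to 24 at 12 weeks, and 217 to 252 across times. At 6 weeks the lowest counts in WT DMM vs sham, KO DMM vs sham, KO vs WT sham and the interaction came without WT DMM replicate 1, KO sham replicate 2, KO sham replicate 3 and WT DMM replicate 3, and the 10 calls in KO vs WT DMM without WT DMM replicate 2. At 12 weeks the highest counts came, in the order of the comparisons, without WT DMM replicate 2, KO DMM replicate 1, KO DMM replicate 3, KO sham replicate 1 and KO DMM replicate 1, and the counts of 0 without WT sham replicate 2 for WT DMM vs sham and without WT DMM replicate 3 for KO vs WT DMM and the interaction. Leaving out WT sham replicate 3 at 6 weeks was not run, since it leaves that group without a library. Splits of 6 libraries gave up to 2 calls in KO vs WT DMM and 7 in KO DMM vs sham at 6 weeks (1 and 3 of 10 as large as the real split), and up to 11, 20, 26 and 8 at 12 weeks (7, 8, 9 and 5 of 10 as large), too few splits for a share under 0.05. Shares of signs over the 200 transcripts with the smallest p were 48.5% and 62.5% at 6 weeks, against 50 and 64 of the 100 called. The called transcripts behind the other shares numbered 2 or 4, too few to say whether these shares depend on the list. Over the transcripts ranked highest in each comparison and the alternatives run for each, 0 results changed direction, 163 lost their call, 29 gained one and 387 did neither. These transcripts were picked for large fold changes or small p in the main fits, and the alternatives reuse most of the same libraries. A change of direction was therefore unlikely from the start, and its absence is no evidence of robustness. Camera and fry on the fixed gene lists were not run, since no gene could be named.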

Other observations

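The tests on groups at 0 and the account of the locus were chosen after the result was seen. The splits by surgery were written down before their results.

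Splits by surgery set DMM and sham libraries of the same genotype and number apart, whereas splits by genotype keep them together. Splits that keep them together separated a median of 602.5 transcripts at 6 weeks and 110.5 at 12 weeks, against 300 and 61 over all splits, so the counts for surgery and genotype are not comparable. At 12 weeks 57 of 40066 transcripts separated all 6 DMM from all 6 sham libraries (28 higher, 29 lower), and 261 of 462 splits separated as many. At 6 weeks 171 of 39074 did so, and 203 of 210 splits separated as many, so chance cannot be excluded at either time. Splits that keep libraries of the same genotype and number together are among these splits and tend to separate more, which weighs against surgery. The splits therefore cannot decide whether surgery has an effect. MSTRG.1606.1, which edgeR called lower in WT DMM at 12 weeks, lay at 0.644 to 1.47 CPM in the 6 DMM libraries at 12 weeks and at 10.4 to 25.4 CPM in the 6 sham libraries, whereas at 6 weeks it ranged from 0.420 to 13.5 CPM in DMM and from 1.33 to 10.2 CPM in sham.

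Of 40617 transcripts with a mean above 1 CPM, 323 separated the 12 libraries at 12 weeks from the 10 at 6 weeks, 299 of them higher at 12 weeks, while none separated all KO from all WT or all DMM from all sham. Random splits into 12 and 10 separated 0.0800 on average and at most 2. Time and sequencing run cannot be told apart, since each time point was sequenced by itself.

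In the locus of MSTRG.2007.18, another assembled transcript of the same locus was present in KO DMM at 6 weeks, where MSTRG.2007.18 was at 0. MSTRG.2007.17, chosen after its values were seen, was at 51.7 ± 30.3 CPM (SD, n = 3) in KO DMM and 0.458 ± 0.0961 CPM (SD, n = 3) in WT DMM, and its difference did not pass by edgeR (adjusted p = 0.135) and passed by DESeq2 (adjusted p = 4.60e-24). It also passed in the genotype by surgery interaction at 6 weeks by edgeR (adjusted p = 0.0267), which rests on 1 WT sham library. The sum of both was 51.7 ± 30.3 CPM in KO DMM and 87.3 ± 6.37 CPM in WT DMM. The same exchange was present in a WT library: at 12 weeks WT DMM replicate 1 had MSTRG.2007.17 at 89.1 CPM and MSTRG.2007.18 at 0, with the other WT DMM replicates at 0.629 and 0.686 CPM of the former and 57.1 and 87.4 CPM of the latter. A hypothesis is that reads of the locus were assigned to either model as a whole, which may make a transcript appear absent in a library. Over the authors' calls, the share of called siblings moving in opposite directions, 48.2% at 6 weeks and 65.2% at 12 weeks, lay within the range of shuffled directions, and this does not decide the hypothesis, since siblings with UCSC names were not linked to loci.

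Transcripts at 0 throughout a group were compared with sets of libraries that ignore the groups. At 6 weeks the group with the most transcripts at 0 in its 3 libraries and at 0.5 CPM or more in every other library was KO DMM with 8, and 38 of 120 sets of 3 libraries had as many, with up to 37. At 12 weeks it was KO DMM with 5, and 41 of 220 sets had as many, with up to 12. Chance can therefore not be excluded for transcripts at 0 in a group as a set.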
